A study of Mus musculus with 2 samples.

How the data were processed

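Single-cell RNA sequencing was done on mouse regulatory T (Treg) cells, the T cell lineage that restrains other immune cells and depends on the transcription factor Foxp3. The cells had been labelled with MitoTracker, a fluorescent dye that accumulates in mitochondria, and sorted by flow cytometry into a dye-high and a dye-low population, called Mito-high and Mito-low here. Each population gave 1 library, for which 12000 sorted cells were loaded on the Chromium Single Cell 5′ kit version 2 of 10x Genomics, which reads transcripts from their 5′ end and tags each molecule with a unique molecular identifier (UMI). Tissue, strain, sex and age of the mice are not given in the sources used here.

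The deposited values are raw UMI counts per gene and barcode, per the file headers, written by Cell Ranger 7.1.0 with 32285 features in each library. The submitters' processing notes also name Seurat 4.3.0.1 and the mm10 genome. The annotation release, the treatment of intronic reads and any filter on barcodes are not given in the sources used here. The numbers of barcodes, 12352 and 11901, are close to that of the cells loaded and are not those of all droplets, so free RNA could not be measured in empty droplets. The Mito-high number exceeds the 12000 cells given as loaded, so the loaded number, or the reading of each barcode as 1 cell, cannot hold as stated.

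Barcodes with fewer than 500 detected genes or with more than 20% of UMIs from mitochondrially encoded (mt-) genes were left out. Scrublet's method as provided in scanpy 1.11.5 was run on each library alone with an expected doublet rate of 0.08. It marked 0 barcodes in the Mito-high and 1 in the Mito-low library, under the 0.5% below which the caller was taken not to have worked, so no barcode was removed by it. The remaining cells of both libraries were clustered together: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes without mt-, Rpl/Rps, T cell receptor and immunoglobulin segment genes were reduced to 30 principal components, and Leiden clustering used 15 neighbours and resolution 0.6 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). No integration was applied, since with 1 library per group library and group cannot be told apart. Clusters were to be named from marker lists. The class of Treg-like cells failed its check, because the 10 leading genes of cluster 0 held 2 markers of conventional CD4 T cells and 0 Treg markers. The lack of Treg markers does not set cluster 0 apart. Leading genes were ranked by fold against all other kept cells, and those of every cluster held 0 Treg markers. The planned fallback was therefore used: the comparison took all kept cells outside the B cell-like cluster, called T cells below, and clusters are referred to by number and leading genes.

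UMIs were summed over the T cells of each library and scaled to counts per 1000000 UMIs (CPM). The log2 ratio of Mito-high over Mito-low was formed with a pseudo-count of 1 added to each sum. Sums have exact Poisson 95% intervals, ratios exact conditional-binomial intervals and shares exact Clopper-Pearson intervals. A count of 0 is given with the limit of 3 counts. All intervals cover counting error only. With 1 library per group there was no replicate check, no test between groups, no p-value and no standard error; a ratio of at least 1.5-fold is used only to describe size. The spread of ratios is described over genes at 20 CPM or more in at least 1 library.

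Before the data were examined, 49 gene lists were fixed, 34 of genes of known function or RNA quality and 15 of cell type markers. For lists with at least 5 members at 10 CPM or more, the median log2 ratio of those members is given with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. The percentile describes these 2 libraries and is not a test. The lists overlap: Foxp3, for example, belongs to 3 of them. Genes named in the text follow a rule fixed at the same time: the 12 largest and 12 smallest ratios among named genes at 20 CPM or more with at least 10 UMIs in each library, up to 4 members of each list with the largest absolute ratio, 14 genes chosen in advance for Treg biology, copper and mitochondria, and the 5 leading genes of each cluster. Other genes are named with the remark that they were chosen after their values were seen.

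Genes per cell were compared after each cell was thinned at random to 2000 UMIs, and shares of cells with a UMI were compared both as measured and after this thinning. Alternatives covered the scaling (edgeR 4.0.16 TMM under R 4.3.3, median ratio set to 0, CPM without mt-, ribosomal, T cell receptor and immunoglobulin genes), the cells taken, the filters on genes, mt share and expression, the weighting of cells and the clustering settings. Further alternatives were chosen after the data were seen: cells of 4000 to 6000 UMIs, cells outside the cluster led by Gm42418, cluster 1 alone, clusters weighted alike in both libraries, ratios relative to genes of like transcript length, cell cycle medians over unchanged members, the 8% of cells with the highest doublet scores left out, and clustering without genes at least 1.5-fold apart. In a test of RNA quality, also chosen then, T cells were put into 10 equal bins of the share of Malat1, Gm42418 and Lars2 among their UMIs, and the bins were weighted alike in both libraries. Transcript length was the longest protein-coding transcript of each gene in the GENCODE vM21 annotation, and positions are 1-based on GRCm38 (mm10).

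On simulated libraries of the observed depths with 200 of 5455 genes altered, the ratio intervals covered the true value for 94.7% of genes, and the direction was right for 100% of genes altered 1.5-fold. Of 100 unchanged lists of 20 genes, 95% lay inside the central 95% of random lists. The simulated sums were independent Poisson counts, the model that the intervals assume. They check the computation, and not the spread between cells or genes that vary together. Total UMIs were 89996794 and 60688904, so counting error is small for sums over a library, and differences between libraries prepared apart are not covered by it. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.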

Results

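Transcriptomes of single Treg cells with high and low MitoTracker signal were compared, with 1 library of each population. The series title names copper and the suppressive capacity of these cells as its subject. The Mito-high library held 12352 barcodes and 89996794 UMIs (95% Poisson interval 89978201 to 90015389), and the Mito-low library 11901 barcodes and 60688904 UMIs (60673636 to 60704175). After 120 and 209 barcodes with too few genes and 15 and 13 with a high mt share were left out, 12217 Mito-high and 11679 Mito-low cells were kept. Kept Mito-high cells had a median of 6132 UMIs and 2006 genes, and kept Mito-low cells 4668 UMIs and 1814 genes, a ratio of UMIs of 1.31. Thinned to 2000 UMIs per cell, the order of genes per cell turned: the medians were 950 in Mito-high and 1028 in Mito-low, with 139 and 491 shallower cells left out. No library was replicated, so every difference below is one between 2 libraries, and none could be held against a spread between replicates.

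The first comparison asked how the transcriptome of the dye-high cells differed from that of the dye-low cells. Genes of resting and lymph node-homing T cells were higher in the Mito-high library. Of 18 measured resting T cell genes, 12 were at least 1.5-fold higher, 5 lay between, and 1 was at least 1.5-fold lower. Their median log2 ratio was 1.18, at percentile 100 of the random lists. Igfbp4, which encodes an insulin-like growth factor binding protein, was at 80.0 CPM against 5.98 CPM (log2 ratio 3.74, interval 3.59 to 3.90). Ccr7, the chemokine receptor that guides T cells to lymph nodes, was at 449 against 131 CPM, and Satb1, a chromatin organiser of T cells, at 544 against 163 CPM. The exception was Il7r, the interleukin-7 receptor, with a log2 ratio of −1.26, which was named after its value was seen. The overlapping markers of conventional CD4 T cells had a median of 1.26 over 8 members, with Nsg2 at 1.31 and Dapl1 at 2.30. Of these 8, 5 were at least 1.5-fold higher and 2 lower, Il7r and, also named after its value was seen, Cd40lg at −0.88.

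Genes through which Treg cells suppress and settle in tissues were lower in the Mito-high library. Of 35 measured Treg suppressive and effector molecules, 30 were at least 1.5-fold lower, 5 lay between and 0 were 1.5-fold higher, with a median log2 ratio of −1.14 at percentile 0.0. Il10, an anti-inflammatory cytokine, was at 15.9 CPM in Mito-high and 125 CPM in Mito-low (log2 ratio −2.97, interval −3.06 to −2.89). Klrg1, a receptor of terminally differentiated lymphocytes, was at 15.4 against 107 CPM, and Tigit, an inhibitory receptor, at 8.43 against 45.1 CPM. Fgl2, a secreted suppressive protein, was at 3.98 against 27.0 CPM. Among genes with cytotoxic or T helper functions, 6 were measured and 4 were at least 1.5-fold lower: Ccl5, Tbx21, Ifng and Gzmb, with log2 ratios of −3.86, −3.06, −2.08 and −1.62. Of 18 chemokine receptors and integrins, 10 were lower and 1, Ccr7, was higher. Their median was −0.87 (−0.09 with clusters weighted alike and −0.22 in cluster 1 alone). Cxcr3 was at −1.86, Cxcr6 at −1.81 and Itgae, the integrin chain that binds epithelial cadherin, at −1.54.

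Foxp3 itself was at 25.8 CPM (24.8 to 26.9) in the Mito-high and 41.0 CPM (39.4 to 42.7) in the Mito-low library, from 2318 and 2483 UMIs, a log2 ratio of −0.67. Ctla4, an inhibitory receptor of Treg cells, had a ratio of −0.57, and Ikzf2, which encodes Helios, −0.52. Il2ra, the high-affinity interleukin-2 receptor chain, went the other way with 0.42. In cluster 1 alone and with clusters weighted alike, Ikzf2 came to 0.08 and −0.03, while Ctla4 stayed lower at −0.26 and −0.23. Of 15 transcription factors of Treg identity, Satb1 and Bach2 were at least 1.5-fold higher in Mito-high (1.74 and 1.15) and Nfatc1, Gata3 and Foxp3 lower, with −0.94 for Nfatc1 and −0.71 for Gata3. The median of the 15 was −0.31 (percentile 3.09), but −0.01 both in cluster 1 alone and with clusters weighted alike. Among cells of 4000 to 6000 UMIs it was −0.13 (percentile 41.9), and among lists matched on transcript length too it stood at percentile 19.9. The median of 10 Treg markers was −0.62 (percentile 0.03). A Foxp3 UMI was found in 16.0% of Mito-high T cells (15.4 to 16.7) and 17.3% of Mito-low T cells (16.7 to 18.05), at median depths of 6136.5 and 4668 UMIs. After thinning to 2000 UMIs the shares were 5.02% and 8.12%. In the B cell-like cluster, which should lack the gene, 0 of 23 cells at a median of 3104 UMIs had one, which allows up to 13.0% before and 13.6% after thinning. These limits lie below the shares before thinning and above those after it.

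Signs of RNA quality also differed. Gm42418, a locus that overlaps ribosomal RNA sequence, made up 0.146% of UMIs in Mito-high and 0.402% in Mito-low, and the nuclear transcript Malat1 0.959% and 1.81%. Lars2 was at 48.3 and 88.6 CPM. These 3 genes were singled out after their values were seen. Without the cells of the cluster led by Gm42418 and Lars2, the medians of the resting and effector lists were 1.25 and −1.15. Genes of dissociation and heat stress were lower in Mito-high, with a median of −0.45 over 17 members. Of these, 6 were at least 1.5-fold lower, among them Atf3 at −1.46 and Hspa1b at −0.89, and 11 lay between. Among cells of 4000 to 6000 UMIs the stress median was −0.21, at percentile 24.7 of random lists there, and 6 members were above 0.

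**Figure D1:**
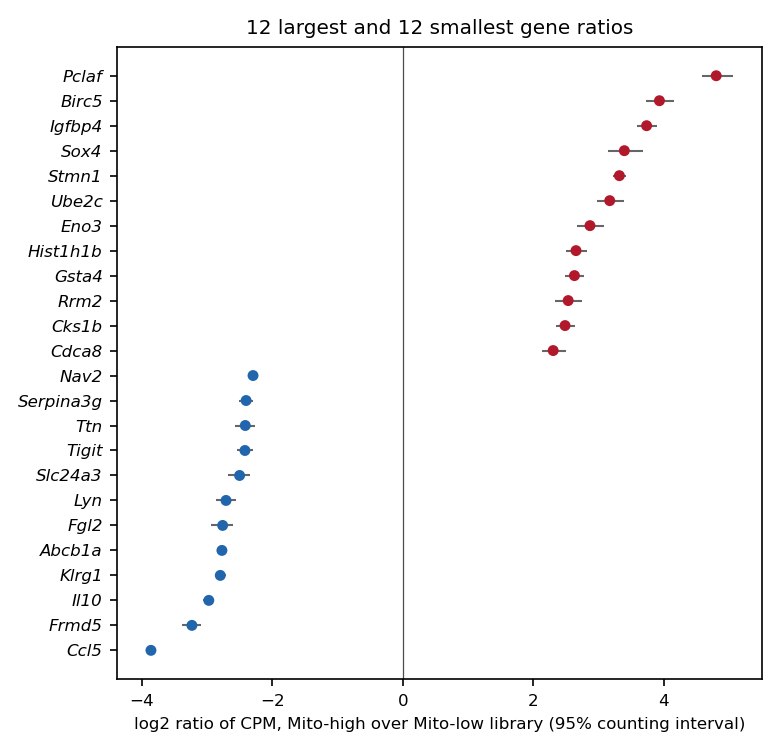
Log2 ratio of CPM, Mito-high over Mito-low, of the 12 genes with the largest and the 12 with the smallest ratios under the naming rule. Points are ratios and lines 95% counting intervals; Pclaf lies at 4.80 and Ccl5 at −3.86.

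Proliferation genes gave most of the largest ratios. Pclaf, a partner of the replication clamp, was at 69.7 CPM in Mito-high against 2.48 CPM in Mito-low (log2 ratio 4.80, interval 4.58 to 5.06). Birc5 (survivin) followed with 47.3 against 3.07 CPM, and Stmn1, a microtubule regulator, with 167 against 16.7 CPM. Of 19 S phase genes, 12 were at least 1.5-fold higher and 0 lower (median 1.10), with Uhrf1 at 2.85 and Rrm2 at 2.54. Of 12 measured genes of G2 and M phase, 9 were higher and 0 lower (median 1.73), with Ccna2 at 4.62 and Ube2c at 3.17. Both lists stood at percentile 100. Outside the cycling cluster Pclaf, Birc5, Ube2c and Stmn1 stayed higher in Mito-high, at 3.05, 2.24, 2.18 and 2.06, while Rrm2 came to −0.07 and Mki67 turned from 1.21 to −0.95. Over the same members the medians there were 0.28 for S phase and −0.20 for G2 and M phase. Among cells of 4000 to 6000 UMIs both were −0.24, but that window lies below the median of 15972.5 UMIs of the cycling cluster.

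The other genes with the largest ratios were Sox4, Eno3, Hist1h1b, Gsta4, Cks1b and Cdca8, with log2 ratios of 3.40, 2.87, 2.66, 2.63, 2.49 and 2.31. At the low end stood Frmd5, Abcb1a, Lyn, Slc24a3, Ttn, Serpina3g and Nav2, with −3.23, −2.77, −2.71, −2.50, −2.41, −2.40 and −2.30. Over 5786 genes at 20 CPM or more the median log2 ratio was −0.15, and the central 95% of genes ran from −1.16 to 0.72. TMM scaling raised every ratio by 0.19, setting the median to 0 raised it by 0.15, and leaving mt-, ribosomal, T cell receptor and immunoglobulin genes out of the total raised it by 0.13.

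The second comparison concerned mitochondria, since the sort was on a mitochondrial dye. The mt-encoded share of UMIs was 3.44% in Mito-high (3.436 to 3.444) and 3.23% in Mito-low (3.223 to 3.232), a ratio of 1.07. Per cell the median was 208 mt UMIs against 148, a ratio of 1.41, while the median share was 3.32% against 3.17%. The 13 mt-encoded protein genes had a median log2 ratio of 0.01, and 0 of them were 1.5-fold apart: mt-Atp6 was at 0.27, mt-Nd6 at −0.19, mt-Atp8 at −0.39 and mt-Nd4l at −0.48.

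Several lists of nuclear genes for mitochondrial proteins had medians slightly above 0. Of 47 mitochondrial ribosome genes, 40 had a positive ratio and 2 were at least 1.5-fold higher, Mrps28 at 0.69 and Mrpl27 at 0.61 (median 0.24, percentile 100). The 22 genes of mitochondrial import and chaperones had a median of 0.26, with 1 at least 1.5-fold higher, Timm8a1 at 0.76, and Hspe1 at 0.57. In cluster 1 alone that median was 0.0005. Among 36 nuclear subunits of complex I the median was 0.12 and 28 were positive; Ndufab1 at 0.61 and Ndufc2 at 0.59 were at least 1.5-fold higher. The 18 subunits of the ATP synthase had a median of 0.21, with Atp5b at 0.51 and 1 at least 1.5-fold lower, Atp5md at −0.75. The 17 genes of the TCA cycle had a median of 0.12, with Sdhd at 1.34 and Idh2 at 0.83. Sdhd, a membrane anchor of succinate dehydrogenase, was also the 1 gene of 14 in complexes II and III that was at least 1.5-fold higher (list median 0.09). The 12 nuclear subunits of complex IV had a median of 0.16, with 0 of them 1.5-fold apart and Cox5a at 0.43. Genes of mitochondrial dynamics and mitophagy had a median of −0.24 over 14 members, with 1 at least 1.5-fold lower, Sqstm1 at −0.83. That median was at percentile 18.1 of random lists, which had a median of −0.15 themselves. Among cells of 4000 to 6000 UMIs the medians were −0.0019 for the mitochondrial ribosome and −0.03 for complex I, still at percentiles 99.99 and 98.6 of random lists there. In the same cells they were 0.06 for import and chaperones, 0.04 for the TCA cycle, 0.008 for the ATP synthase, −0.05 for complex IV and −0.08 for complexes II and III, at percentiles 99.9, 99.3, 94.1, 65.4 and 79.0, and 3 of the 12 complex IV subunits were above 0. This window also selects cell states, as the median depth in Mito-high was 5337 UMIs in cluster 0 and 7291 in cluster 1. Within clusters 0, 1, 2, 3 and 6 the mitochondrial ribosome median was 0.093, 0.182, 0.403, 0.456 and 0.292, and that of complex I 0.05, 0.095, 0.292, 0.33 and 0.165. Ratios also ran with transcript length, with a Spearman correlation of −0.30 across 5646 genes, which are not independent replicates. In the same clusters, in this order, the correlation was −0.054, −0.216, −0.456, −0.414 and −0.252. Over all T cells, among lists matched on length too, complex I stood at percentile 91.8, the ATP synthase at 98.4 and the mitochondrial ribosome at 100.

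Metabolic lists with medians near 0 were glycolysis and fatty acid oxidation, while their random lists had medians of −0.14 and −0.15. Glycolysis had a median of 0.00 over 16 genes (percentile 94.5), with 0 of them 1.5-fold apart and Ldha at 0.47. Fatty acid oxidation had 0.05 over 16 genes (percentile 98.1), also with 0 apart and Etfa at 0.46. The latter median was −0.08 after thinning, and that of glycolysis was −0.25 among cells of 4000 to 6000 UMIs, with 2 of 16 above 0. The regulators of mitochondrial biogenesis had a median of −0.13 over 8 genes that turned positive under all 3 other scalings, with 1 at least 1.5-fold lower, Esrra at −0.59. Tfam, the packaging factor of mitochondrial DNA, was at 43.3 and 43.5 CPM, and its ratio of −0.01 turned positive under the same scalings. Ppargc1a had 29 and 10 UMIs, and its ratio interval of −0.11 to 2.17 includes 0. The 18 antioxidant genes had a median of 0.04 (percentile 97.7), with Prdx3 at 0.76 and Gpx4 at −0.65 as the 2 that were at least 1.5-fold apart. Among cells of 4000 to 6000 UMIs the median was −0.13 (percentile 69.7).

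**Figure D2:**
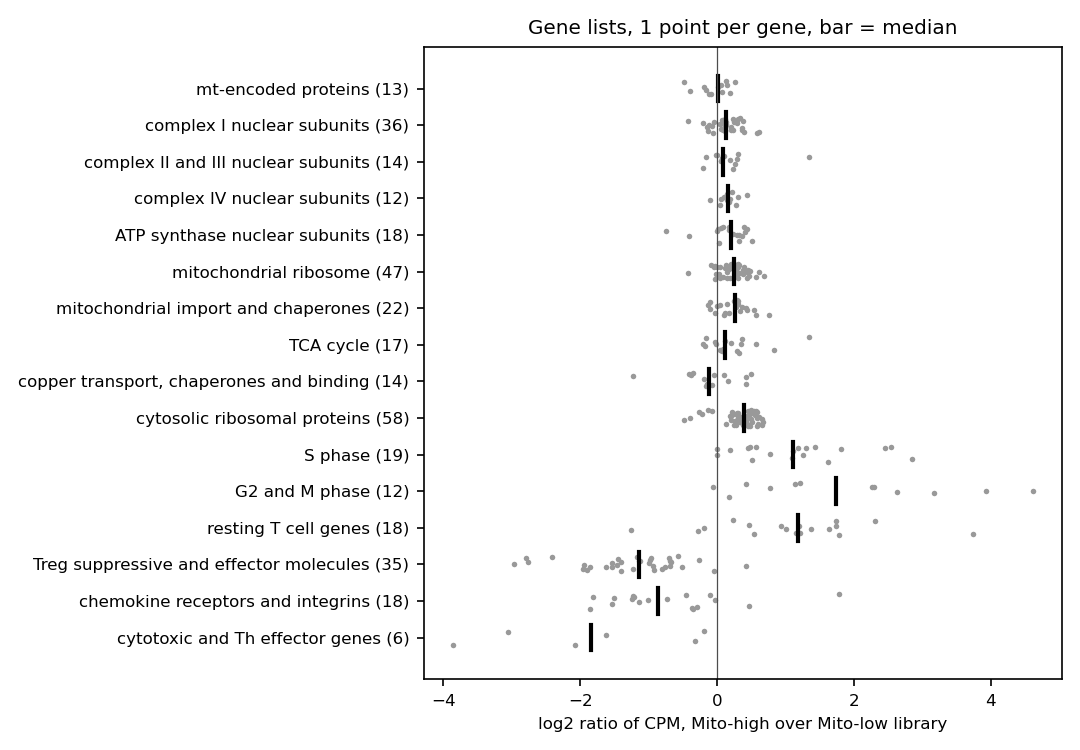
Log2 ratio of CPM, Mito-high over Mito-low, of the genes of 16 lists, with 1 point per gene, the number of measured genes in parentheses and a bar at the median. The medians of the mitochondrial lists drawn lie between 0.01 and 0.26, those of resting and effector genes at 1.18 and −1.14; the copper median of −0.11 turns positive under the other scalings.

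The third comparison concerned copper genes, which the series title names. Of 14 measured genes of copper transport, chaperoning and binding, 0 were at least 1.5-fold higher and 1 was lower, and the median of −0.11 became 0.08, 0.04 and 0.02 under the 3 other scalings. Mt1, which encodes a copper- and zinc-binding metallothionein, was at 22.4 CPM (21.4 to 23.4) in Mito-high and 52.5 CPM (50.7 to 54.4) in Mito-low, a log2 ratio of −1.23. Mt2, too low for the list at 1.85 and 4.71 CPM, had −1.35. Both turned positive when clusters weighed alike in the 2 libraries, to 0.26 for Mt1 and 0.51 for Mt2. Among cells of 4000 to 6000 UMIs both lay lower, at −2.32 for Mt1 and −2.58 for Mt2. Slc31a1, the copper importer of the plasma membrane, was at 11.5 and 12.1 CPM, a log2 ratio of −0.07 with an interval of −0.21 to 0.07. The copper exporter Atp7a was at 0.10 (−0.01 to 0.22). The chaperone Atox1 was at −0.04, and its sign and that of Slc31a1 turned under all 3 other scalings. Cox17, which delivers copper to cytochrome c oxidase, was at −0.15. Of the other scalings only TMM turned it positive, to 0.04, and so did clusters weighted alike, to 0.14, and cluster 1 alone, to 0.02. Commd1 was at 0.49 and Memo1 at 0.42. The 17 assembly factors of complex IV had a median of −0.06, which turned positive under the other scalings, with 1 at least 1.5-fold lower, Pet100 at −0.71, and Cox19 at 0.42. Genes of copper-induced cell death had a median of 0.02 over 10 members, with 2 at least 1.5-fold higher, Gcsh at 0.61 and Fdx1, a ferredoxin required for this form of death, at 0.59.

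The fourth comparison was of cell states. Cells were divided into 10 clusters, of which 9 held T cells. Cluster 0, led by Igfbp4, Ly6c1, Satb1, Klf2 and Tubb2a, held 48.3% of Mito-high cells (47.4 to 49.2) and 3.79% of Mito-low cells (3.45 to 4.16). Cluster 3, led by Ccl5, Il10, Klrg1, Penk and Frmd5, held 1.54% (1.33 to 1.77) and 28.3% (27.5 to 29.2). Cluster 2, led by S100a4, S100a6, Ccr2, Lgals3 and Gna15, held 8.77% and 24.0%. Cluster 4, led by Eno3, Lad1, Itm2a, Mettl1 and Hspd1, held 10.9% and 1.09%. The cycling cluster 7, led by Pclaf, Birc5, Stmn1, Hist1h1b and Hist1h2ae, held 501 cells (4.10%) and 25 cells (0.214%), at a median of 15972.5 UMIs per cell. Cluster 1, led by Ryr2, Gm49180, Tbc1d4, C2cd4b and Hdac9, was the most evenly shared of these, with 20.9% and 25.6%.

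Clusters 5, 6 and 8 leaned to the Mito-low library. Cluster 5, led by Gm42418 and Lars2, with Cmss1 and Cdk8 also among its leading genes, held 1.87% of Mito-high and 7.41% of Mito-low cells at a median of 3530 UMIs. Cluster 6, led by Gbp2b, Adam12, Myo3b, Ccr4 and Maf, held 2.20% and 6.65%, and cluster 8, led by Ifit1, Hspa1a, Hspa1b, Ifit3 and Isg15, 1.20% and 2.94%. Cluster 9, B cell-like and led by H2-Aa, H2-Ab1, Ebf1, H2-Eb1 and Mef2c, held 23 Mito-high and 0 Mito-low cells, which allows up to 0.026% of the latter. As genes that differ between libraries can themselves draw the clusters, clustering was repeated without genes at least 1.5-fold apart. It gave 8 clusters: 2 clusters led by Igfbp4 held together 49.3% of Mito-high and 13.2% of Mito-low cells, the cluster led by Gm42418 10.8% and 9.59%, the cluster led by Il10 and Klrg1 2.21% and 28.9%, and the cycling cluster 9.65% and 2.95%.

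**Figure D3:**
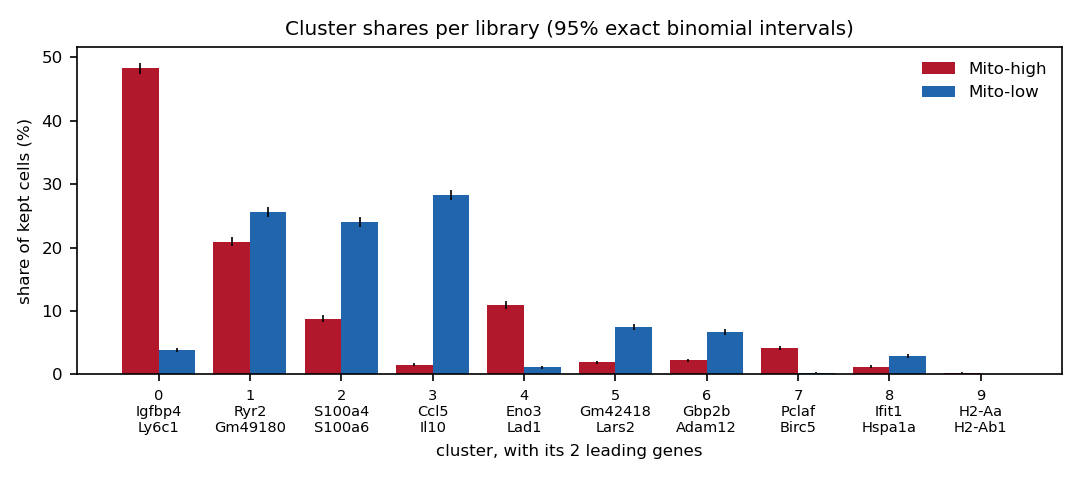
Share of kept cells (%) of each library in the 10 clusters, with exact binomial 95% intervals and the 2 leading genes of each cluster. Cluster 0 holds 48.3% of Mito-high and 3.79% of Mito-low cells and cluster 3 holds 1.54% and 28.3%; clustering without differing genes gave 49.3% and 13.2% for the Igfbp4-led clusters together and 2.21% and 28.9% for the Il10-led cluster.

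Within clusters the resting and effector lists differed less than between whole libraries. Some of this can follow from the clustering itself, as members of these lists, such as Igfbp4, Satb1, Il10 and Klrg1, lead clusters 0 and 3. The median of the effector list, over the members measured across all T cells, was −0.22 in cluster 0, −0.26 in cluster 1, −0.32 in cluster 2, −0.16 in cluster 3 and −0.64 in cluster 6. The median of the resting list was 0.07, 0.71, 0.13, 0.15 and 0.58 in the same clusters. With the 8 clusters of at least 100 cells in each library weighted alike, the medians were −0.22 for effector and 0.25 for resting genes. Over all T cells they were −1.14 and 1.18.

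Abcb1a (ENSMUSG00000040584; chromosome 5, 8660077 to 8748575, plus strand), which encodes the efflux pump P-glycoprotein, differed within clusters as well as between libraries. It was at 17.3 CPM in Mito-high (16.5 to 18.2, from 1556 UMIs) and 118 CPM in Mito-low (116 to 121, from 7167 UMIs), a log2 ratio of −2.77 (−2.85 to −2.69). In cluster 1, with 2556 and 2984 cells, it was at 23.9 and 109 CPM (log2 ratio −2.18, interval −2.33 to −2.04), the lowest of 5488 ranked genes. In all 8 clusters with at least 100 cells in each library it was at least 1.5-fold lower in Mito-high, with ratios from −2.84 in cluster 5 to −1.73 in cluster 2. The list of 7 drug efflux pumps had a median of −0.33 (percentile 12.7), with 2 at least 1.5-fold lower, Abcb1a and its paralog Abcb1b, the latter at 24.4 and 41.4 CPM, a ratio of −0.76. Abcg2, named after its value was seen, was at 8.02 and 7.98 CPM.

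**Figure D4:**
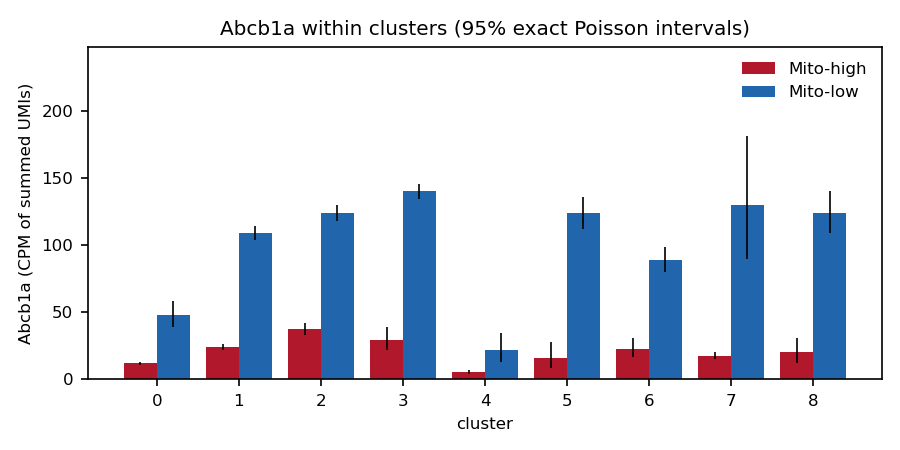
Abcb1a in CPM of the UMIs summed within each cluster and library, with exact Poisson 95% intervals. In each T cell cluster shown the Mito-high bar is the lower one, as in cluster 1 at 23.9 against 109 CPM; cluster 7 holds 25 Mito-low cells.

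The positions of the genes with the values given above are, on GRCm38, chromosome X, 7573644 to 7595245 for Foxp3 (ENSMUSG00000039521), chromosome 1, 131019845 to 131024974 for Il10 (ENSMUSG00000016529), chromosome 6, 122270596 to 122282882 for Klrg1 (ENSMUSG00000030114), chromosome 11, 99041244 to 99054392 for Igfbp4 (ENSMUSG00000017493), chromosome 9, 65890237 to 65903266 for Pclaf (ENSMUSG00000040204), chromosome 8, 94179082 to 94180327 for Mt1 (ENSMUSG00000031765) and chromosome 4, 62360727 to 62391769 for Slc31a1 (ENSMUSG00000066150).

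Markers of other cell types were low among the T cells, and the 10 general T cell markers had a median log2 ratio of −0.21, with Cd3e at −0.58. Summed over each list, markers of CD8 T cells came to 11.9 CPM in Mito-high and 7.47 CPM in Mito-low, those of gamma-delta T cells to 5.80 and 5.01, plasma cells to 1.63 and 1.31, neutrophils to 0.468 and 2.20, erythroid cells to 1.82 and 7.32 and platelets to 1.10 and 1.06. The lists of monocytes and macrophages summed to 24.2 and 23.1 CPM, mostly Ms4a6c at 17.1 and 14.97, dendritic cells to 60.6 and 101, mostly Cd74 at 50.1 and 82.5, and thymocytes to 121 and 105, mostly Themis. The natural killer and innate lymphoid list, at 97.3 and 256 CPM, was almost wholly Areg, which the effector list also holds. The stromal, epithelial and endothelial list came to 182 and 175 CPM, mostly Pecam1 at 171 and 134, with Epcam at 9.56 and 38.7. The B cell list came to 172 and 355 CPM, of which the immunoglobulin gene Ighm gave 149 and 314.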

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

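The tests of Ighm were chosen before their results were seen, and Ighm, Igkc and Cd79a were named after their values were seen. Immunoglobulin genes were left out of the comparisons, yet Ighm, the heavy chain gene of IgM, gave a UMI in 41.2% of Mito-high T cells (40.3 to 42.0) and 60.3% of Mito-low T cells (59.4 to 61.2). The median depths were 6136.5 and 4668 UMIs, and after thinning to 2000 UMIs the shares were 19.7% and 39.3%. Within clusters the thinned shares did not all follow this order: they were 41.2%, 48.7% and 47.7% in Mito-high against 36.5%, 43.3% and 42.0% in Mito-low for clusters 2, 3 and 6, and lower in Mito-high in the other 6, as in cluster 1 at 30.04% against 39.73%. In the B cell-like cluster 22 of 23 cells had an Ighm UMI. Igkc gave a UMI in 2.22% of Mito-high and 4.48% of Mito-low T cells, and Cd79a in 0.828% and 0.385%. A sort for Treg cells should remove B cells.

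Free RNA from B cells would carry Ighm together with other B cell transcripts in the ratio found in B cells. The ratio of Ighm to the summed UMIs of Cd79a, Cd79b, Ms4a1, Cd74, H2-Aa and H2-Ab1 was 2.34 in Mito-high T cells and 3.11 in Mito-low T cells, against 0.0767 in the B cell-like cluster, so the smaller of both was 30.5 times that of the cluster, which argues against free RNA of such cells as the source. Some of these genes, Cd74 among them at 50.1 and 82.5 CPM, also had UMIs in T cells, which can only make the T cell ratio smaller. Transcription of the Ighm locus in some T cell states may account for the UMIs. After thinning, the share of cells with one, over both libraries together, ranged 4.004-fold between clusters of at least 500 cells. It ran from 10.9% in clusters 0 and 4 to 43.6% in cluster 3. For clusters 0 and 3 it was 10.3% and 48.7% in Mito-high alone, and 18.6% and 43.3% in Mito-low alone. Whether these reads are rearranged heavy chains or transcripts of the unrearranged locus, and whether antibody-secreting cells gave free RNA of another make-up, stays open; markers of plasma cells summed to 1.63 and 1.31 CPM.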

How the results depend on the processing

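Cells of 4000 to 6000 UMIs, cluster 1 alone, clusters weighted alike, the cluster led by Gm42418 left out, ratios relative to like transcript length, cell cycle medians over unchanged members, the top 8% of doublet scores left out and clustering without differing genes were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because there was 1 library per group. Marked doublets were kept in the values reported, Treg-like cells alone were not taken as a set because that class failed its check, and cluster 3 had no counterpart at resolution 0.3. Of 684 values of list medians, 594 stayed within the spread of the list, 72 moved and 18 reversed; of 629 values of named genes, 379 stayed within the counting interval, 239 moved and 11 reversed. The effector median was negative and the resting median positive under all 20 alternatives, from −1.53 to −0.21 and from 0.25 to 1.49, and Abcb1a ran from −3.07 to −2.10. Where no cause is named, the cause was not tested. Depth limits genes such as Ppargc1a, with 29 and 10 UMIs, and the 25 Mito-low cells of the cycling cluster.

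With TMM scaling, the median set to 0 and the total without mt-, ribosomal and receptor genes, in this order, the median over genes was 0.041, 0.00 and −0.015, the bounds of the central 95% −0.97 and 0.91, −1.01 and 0.87, and −1.03 and 0.85, and the mitochondrial ribosome 0.44, 0.39 and 0.38, by construction. In cluster 1 alone the median over genes was −0.046 with bounds of −0.65 and 0.52, and the list medians were 0.18 (mitochondrial ribosome), −0.21 (effector), −0.065 (G2 and M phase) and −0.31 (MYC); Rrm2 was at −0.29 and Mt2 at 0.23. With clusters weighted alike the median over genes was −0.038 with bounds of −0.54 and 0.46, and the lists gave −0.22 (effector), 0.25 (resting), −0.20 (G2 and M phase) and −0.26 (MYC); Mt1 was at 0.26, Mt2 at 0.51 and Mki67 at −0.10. Both settings take out the different cluster shares. Both also leave out the cycling cluster 7, since only clusters with at least 100 cells in each library were weighted alike. The values for G2 and M phase, MYC and Mki67 in these settings thus lack its cells. With genes of at least 10 UMIs and no filter on CPM the bounds were −1.79 and 1.60.

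Among cells of 4000 to 6000 UMIs the lower bound over genes was −1.48, and the lists gave −0.034 (complex I), −0.13 (fatty acid oxidation), −0.0019 (mitochondrial ribosome), −0.13 (antioxidant), −1.53 (effector), −0.42 (S phase, 12 members left of 19) and −0.59 (G2 and M phase, 5 left of 12), or −0.235 and −0.241 over all members measured among T cells; Hist1h1b was at −0.87, Rrm2 at −0.086 and Mki67 at −1.52. Outside the cycling cluster fatty acid oxidation was at 0.00, the mitochondrial ribosome at 0.17, G2 and M phase at −0.40, or −0.20 over all its members, Hist1h1b at −0.035, Rrm2 at −0.066 and Mki67 at −0.95. Thinning to 2000 UMIs and the mean of each cell's CPM gave −0.084 and −0.021 for fatty acid oxidation, 0.16 and 0.16 for the mitochondrial ribosome and 0.43 and 0.42 for G2 and M phase. At 50 CPM fatty acid oxidation was at −0.029 and G2 and M phase at 0.30.

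The difference in mt-encoded share, 0.212 percentage points, was 0.232 with at most 5% mt UMIs, 0.203 with a minimum of 200 genes and 0.225 with 1000. The difference in median genes per cell, −78 after thinning, was −77 with a minimum of 1000 genes, −45 thinned to 1000 UMIs and 192 unthinned, where depth differs; the ratio of median UMIs was 1.297 with a minimum of 1000 genes. The difference in the share of cluster 0, 44.5 points, was 57.3 at resolution 0.3, 40.4 at 1.2, 51.0 without a filter on mt share, 52.0 with at most 10%, 51.4 without cell cycle genes, 52.2 without the top doublet scores and 37.4 without differing genes, where the counterpart includes a cluster led by Gm42418. That of cluster 3, −26.8, was −24.4 without a filter on mt share and −22.3 without the top doublet scores. That of the cycling cluster, 3.89, was 3.24 without cell cycle genes and 6.70 without differing genes.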

Other observations

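Some tests in this part were chosen after the result was seen. They are those of cluster shares for Abcb1a, mitochondria per cell, Foxp3 by cluster and the share of Malat1, Gm42418 and Lars2. The cells of 4000 to 6000 UMIs and those outside the cluster led by Gm42418 were also chosen then. The other tests were chosen before. Several gene groups outside the subjects of the comparisons also differed. Interferon-induced genes were lower in the Mito-high library: of 16 measured, 4 were at least 1.5-fold lower, 12 lay between and 0 were higher (median log2 ratio −0.37, percentile 1.62). The 4 were Oas1a at −1.70, Ifit1 at −1.26, Isg15 at −1.20 and Ifit3 at −0.82, and among cells of 4000 to 6000 UMIs the median was −0.21 at percentile 36.4. Cytosolic ribosomal protein genes were higher, with 52 of 58 above 0 and 8 at least 1.5-fold higher (median 0.40), among them Rpl15 at 0.68 and Rplp0 at 0.66. Their median ran from 0.14 with clusters weighted alike to 0.59 with TMM scaling. It was 0.20 with T cells weighted alike by the share of Malat1, Gm42418 and Lars2. Of 17 genes of the MYC and nucleolar growth programme, 5 were at least 1.5-fold higher and 1 lower (median 0.15). Myc was at 46.4 against 23.1 CPM, Srm, the spermidine synthase, at 20.5 against 10.4 CPM and Npm1 at 1470 against 904 CPM, with Nop16 at 0.70 and Eif4a1 at 0.59 named after their values were seen. Odc1, the enzyme one step before spermidine synthase, went the other way with 317 against 717 CPM, and within cluster 1 the list's median was −0.31. Among genes of cholesterol synthesis, Idi1 at 0.92, Fdps at 0.83 and Hmgcs1 at 0.62 were at least 1.5-fold higher.

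Of 17 genes of T cell receptor activation, 3 were at least 1.5-fold higher, Myc at 1.003, Dusp2 at 0.93 and Nr4a1 at 0.62. Lower were 4, Nfkbid and Tnfrsf9 at about −0.93, Cd40lg at −0.88 and Cd44 at −0.60. The list median was −0.33 (percentile 1.985), but −0.03 with clusters weighted alike. Among cells of 4000 to 6000 UMIs it was −0.25, at percentile 9.0. Nr4a1, Cd40lg and Cd44 were named after their values were seen. Apoptosis genes went both ways around a median of −0.02 over 17 members, which turned positive under the other scalings. Bcl2, a survival factor, was at 1.20 and Bcl2l11, named after its value was seen, at 0.91, while Cdkn1a, Pmaip1 and Apaf1 were at −2.00, −0.93 and −0.92. Among 11 hypoxia genes (median 0.02), Egln3 at −1.47 and Mxi1 at −1.28 were at least 1.5-fold lower and 0 higher. The unfolded protein response had a median of −0.06 over 15 genes with 1 at least 1.5-fold higher, Sdf2l1 at 0.64, and iron handling −0.08 over 11 with 0 apart and Fth1 at −0.35; both medians turned positive under the other scalings. Some genes, ranked after the data were seen, differed the same way within each of clusters 0, 1, 2, 3 and 6. Snhg6 was higher in Mito-high by log2 ratios of 1.498 to 2.01, Anxa2 by 1.44 to 1.94, the class I gene H2-T23 by 1.23 to 1.41, Myb by 1.20 to 1.99 and Sdhd by 0.96 to 1.88. Lower were Usp2 from −1.89 to −1.26, Rln3 from −1.95 to −1.02 and H2-Q6, another class I gene, from −1.61 to −0.90.

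The pattern of higher resting and lower effector genes in the Mito-high library was held against 3 technical explanations, depth, RNA quality and other cells. If the deeper Mito-high cells caused it, the resting median should shrink among cells of 4000 to 6000 UMIs, but it was 1.49 there. RNA quality was marked by the share of Malat1, Gm42418 and Lars2. If it caused the pattern, weighting T cells alike by this share should move the effector median most of the way to 0. The median went only from −1.14 to −0.98. Genes outside the weighting moved further, Cmss1 from −0.92 to −0.25 and the stress list from −0.45 to −0.16. Leaving out the cluster led by Gm42418 gave an effector median of −1.15 and decides nothing, as this took out 7.41% of Mito-low cells. Conventional CD4 T cells in the Mito-high sort stay open. The resting median was 1.14 among cells with a Foxp3 UMI. But background could give a UMI in up to 13.0% of cells against the 16.0% found in deeper cells. After thinning it could do so in up to 13.6% against 5.02%, so in all of them. Of the conventional markers outside the resting list, Nsg2 (1.31) goes with this explanation and Cd40lg (−0.88) against it. Within Mito-high, Foxp3 was at 29.2 CPM in cluster 0, which held 48.3% of cells. It was lower in clusters 1, 2 and 3, at 25.1, 27.8 and 17.2 CPM, and in clusters 4, 7 and 8. It was higher in clusters 5 and 6, at 40.7 and 40.8 CPM. The Mito-high values of clusters 2 and 3 rest on 225 and 27 UMIs. In Mito-low, Foxp3 was above 29.2 CPM in clusters 0, 1, 2, 3, 5 and 6, at 34.0 to 57.8 CPM, and below it in clusters 4, 7 and 8. Within Mito-high, Foxp3 thus did not set cluster 0 below most other clusters. This cannot show whether conventional cells made up most of cluster 0 or a smaller share. Neither the background nor the make-up of the other clusters is known. A candidate explanation, not tested here, is that the dye-high sort held more Treg cells in a resting state and the dye-low sort more in an effector state, although the Mito-high library also held more cycling cells (4.10% against 0.214%, or 9.65% against 2.95% when clustered without differing genes); the library itself, with 1 per group, cannot be told apart from the sort.

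A dye-low cell may be one that exports the dye rather than one with fewer mitochondria or a lower membrane potential. Some MitoTracker dyes are substrates of P-glycoprotein, though the dye used is not given in the sources used here, and of the efflux pumps at 10 CPM or more the lowest log2 ratio was that of Abcb1a, at −2.77, as this hypothesis requires. The values argue against different cluster shares as the whole cause. Over the clusters with at least 100 cells in each library the highest upper bound of the Abcb1a log2 ratio was −1.20. With clusters weighted alike Abcb1a was at −2.10, while Il10 went from −2.97 to −0.62. As Il10 is a leading gene of cluster 3, its change can follow from how the clusters were drawn and is no yardstick for Abcb1a. Finer states within clusters stay open, since in cluster 1 Igfbp4 was at 3.76 and Il10 at −1.59. In clusters 2 and 3 Abcb1a was at −1.73 and −2.22. Il10 was at −0.33 in both and the effector median at −0.32 and −0.16. But Ccl5, which leads cluster 3, was at −1.723 and −2.205 there. Neither pump activity nor dye content was measured, so export, a lower potential, a difference between libraries unrelated to the dye and fewer mitochondria in dye-low cells, with mt-encoded UMIs per cell 1.41 times and the mt-encoded share 1.07 times as high in Mito-high, stay open too.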
